A study of Homo sapiens with 8 samples.

How the data were processed

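PolyA-selected RNA was sequenced from HCT116 cells with a stably introduced, doxycycline-inducible shRNA against HOXB8, after 72 hours in the presence or absence of 1 ug/ml doxycycline, with 2 hairpins and 2 repeats per group, 8 libraries in all. The deposited values are FPKM, fragment counts that the authors scaled to transcript length and to the mapped fragments of each library, for 17166 genes with RefSeq and Entrez identifiers. Per the submitters' processing notes, HISAT and Bowtie2 were used with genome build hg19; their roles and versions, the quantifier and the annotation release are not given in the sources used here. No coordinates are given, because the build differs from that of the reference at hand. The table names its second hairpin sh3 where the labels say sh2: sh3 was taken as sh2 by elimination, since the rest of each name matches and 2 hairpins are known, but this is not proven. The labels' source description says induced for all 8 samples, while titles and genotypes put 4 without doxycycline; groups follow the titles. A spreadsheet had turned 27 gene symbols into dates, and all 27 were restored from their Entrez identifiers, of which 17131 matched a RefSeq table.

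FPKM columns summed to between 440063 and 446889, and the 10 highest genes took 5.59% to 6.08% of each sum. Total read numbers cannot be recovered from FPKM. The step between the lowest values was read in 24 genes (values from 0.1 FPKM, steps up to 4, tolerance 10%). In these genes the value of 1 read differed between libraries by a factor of 0.992 to 1.01. Genes with a library's step over 10% from the gene's median were passed over, so a larger difference in depth could not be seen. Libraries of the same group correlated at r = 0.996 to 0.998 across genes and libraries of different groups at 0.992 to 0.997. The first principal component held 39.5% of the variance and the second 18.6%.

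Genes with a mean of at least 1 FPKM over the 8 libraries were tested (11712; 5454 were not), on log2(FPKM + 1), in limma 3.58.1 under R 4.3.3 with 1 mean per group over all 8 libraries (4 residual degrees of freedom), empirical Bayes moderation with a trend, two-sided tests and Benjamini-Hochberg adjustment over genes. The threshold was an adjusted p under 0.05 with no fold limit. There were 5 comparisons: the dox effect averaged over both lines, the effect in each line, the difference of these effects (sh2 minus sh1), and the lines without doxycycline (sh2 minus sh1). HOXB8, BACH1, MYC, HOXB7 and HOXB9 were also compared by a two-sided exact permutation test on FPKM, 4 libraries against 4 without regard to the line. Percentages lower are of mean FPKM; log2 changes are of log2(FPKM + 1), so they are smaller for genes of low level. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

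The 24 gene lists, written from general knowledge, were HOX cluster genes, BACH1 and NRF2 antioxidant and heme targets, invasion genes reported as BACH1 targets, proteases and inhibitors of matrix breakdown, mesenchymal and EMT genes, epithelial adhesion and junction genes, MYC targets, Wnt and beta-catenin targets, G2/M and mitosis genes, G1/S and DNA replication genes, p53 targets, interferon-stimulated genes, ATF4 and integrated stress response genes, nuclear OXPHOS genes, cytosolic ribosomal proteins, glycolysis and hypoxia genes, TNF and NF-kB inflammatory genes, cholesterol synthesis genes, ERK with AP-1 and immediate early genes, unfolded protein response genes, TGF-beta response genes, colonic differentiation genes, fibroblast and immune markers not made by epithelial cells, and mitochondrially encoded OXPHOS genes. The last list had 0 of its 26 genes in the table, so 23 were tested. HOXB8 is in no list. Lists were tested with camera at its preset correlation of 0.01 and with an estimated correlation, and with fry, each adjusted over the lists, and members were also adjusted over the list alone. Annotation terms of 10 to 500 tested genes were tested by a one-sided Fisher's exact test against all tested genes with an annotation, adjusted over terms and directions.

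The named genes follow a rule: HOXB8, BACH1, MYC, HOXB7 and HOXB9 always; for the averaged effect the 12 largest rises and 12 largest falls past the threshold with the same sign in both lines; the 5 largest each way for each single line, the difference and the untreated lines; and up to 4 members of each list with the smallest p. Members named because 5 or fewer lay behind a count, ATF4, FTH1 and FTL, further examples beyond this rule, and the members of annotation terms were chosen after their values were seen. HMOX1 was picked after the rise of its list was seen and before its own value was. The comparisons, tests, filter, threshold, lists, naming rule and alternatives were chosen before the data were examined, except the list tests without members that other lists also hold, the splits with no term for the line or within the lines, and the tests of explanations in the closing paragraphs.

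The alternatives were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, quantile normalization, TMM factors computed on FPKM, a term for the replicate number, no term for the line, an additive fit of line and doxycycline, moderation without a trend or with a robust option, the 4 libraries of 1 line alone, and leaving out each library in turn. Count-based tests were left out because the table holds no counts. On simulated data 200 of 11712 genes were changed in each of 3 draws, by 0.5 or 1 on the log2 scale. The noise was drawn independently for each gene. The averaged comparison found 94.0% of changes of 0.5 and all changes of 1. The sh1 comparison found 84.0% and 98.7%, and the difference of effects 70.3% and 95.0%. These had 12.3, 11.0 and 12.7 false calls per draw.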

Results

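PolyA RNA-seq, which reads messenger RNA selected by its tail, was done on HCT116, a human colorectal cancer cell line. The cells carried 1 of 2 short hairpin RNAs (shRNAs) against HOXB8. The hairpins were doxycycline-inducible: the drug switches on the hairpin, which targets the messenger RNA of HOXB8. Each line, called sh1 and sh2, was sampled after 72 hours with 1 ug/ml doxycycline (dox) and without it (no-dox), in 2 libraries per group and 8 in all. Libraries are written as sh1-dox-r2 for the second repeat of the sh1 line with doxycycline, and a number in brackets after a library left out is the adjusted p without it. The values were FPKM, fragment counts scaled to transcript length and to the mapped fragments of the library. Of 17166 genes, 11712 averaged at least 1 FPKM and were tested. Between 15592 and 15762 genes were above 0 in a library, and the number of reads behind them is unknown. The labels call the repeats independent, so the p-values compare the dox effect with the spread between repeats of these lines, not with that between other cell lines. No library had doxycycline without a HOXB8 hairpin, so the effects of the drug and of lower HOXB8 were measured together.

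HOXB8 (Entrez identifier 3218) is the homeobox transcription factor gene that both hairpins target. It averaged 19.2 ± 1.65 FPKM without doxycycline and 6.52 ± 0.678 FPKM with it (SD, n = 4 per state), which is 66.1% lower (log2 change -1.43, SE 0.05, adjusted p = 6.86e-07). In the sh1 line it read 20.8 and 20.4 FPKM without doxycycline and 6.54 and 5.74 FPKM with it. The sh2 line had 17.3 and 18.4 FPKM without and 7.39 and 6.41 FPKM with it. HOXB8 was thus 70.2% lower in the sh1 line and 61.4% lower in the sh2 line. All 4 dox libraries lay below all 4 no-dox libraries (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give).

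The study's title names BACH1 and MYC beside HOXB8. BACH1 (Entrez identifier 571), a repressor of antioxidant and heme genes, averaged 6.34 ± 0.318 FPKM without doxycycline and 4.17 ± 0.101 FPKM with it (SD, n = 4 per state). It was 34.1% lower (log2 change -0.50, SE 0.05, adjusted p = 2.44e-04; exact permutation p = 0.0286). BACH1 fell in both lines, by a log2 change of -0.51 in sh1 (adjusted p = 0.00318) and of -0.49 in sh2 (adjusted p = 0.00595). MYC (Entrez identifier 4609), a growth-promoting transcription factor gene, averaged 167 ± 17.8 FPKM without doxycycline and 147 ± 8.02 FPKM with it (SD, n = 4 per state). It was 12.3% lower (log2 change -0.18, SE 0.03, adjusted p = 0.00691), though its dox and no-dox libraries overlapped (exact permutation p = 0.0857). In a fit with no term for the line the MYC call ended (adjusted p = 0.103). The permutation test and this fit both ignore the line. MYC also differed between the untreated lines, which both count as spread. MYC fell in the sh1 line (-0.26, adjusted p = 0.0147) and read -0.10 in the sh2 line, where it did not pass (adjusted p = 0.278). The difference between the lines was not past the threshold either (adjusted p = 0.992).

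The neighbours of HOXB8 in the HOXB cluster differed far less between the states. HOXB7 (Entrez identifier 3217) averaged 22 ± 1.67 FPKM without doxycycline and 20.5 ± 1.23 FPKM with it (SD, n = 4 per state). It was not past the threshold (log2 change -0.09, SE 0.04, adjusted p = 0.176; exact permutation p = 0.257). HOXB9 (Entrez identifier 3219) averaged 9.96 ± 0.759 FPKM without doxycycline and 11.1 ± 0.547 FPKM with it (SD, n = 4 per state). It rose (log2 change 0.14, SE 0.04, adjusted p = 0.0342; exact permutation p = 0.0857). The call of HOXB9 ended with quantile normalization (adjusted p = 0.0632) and with TMM factors (adjusted p = 0.0604). It also ended with no filter on low values (adjusted p = 0.0561) and with no term for the line (adjusted p = 0.136). The call of HOXB9 was lost without sh1-dox-r1 (0.0695), sh1-dox-r2 (0.0917), sh1-no-dox-r1 (0.135), sh1-no-dox-r2 (0.0634), sh2-dox-r2 (0.0784), sh2-no-dox-r1 (0.109) or sh2-no-dox-r2 (0.0667).

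**Figure D1:**
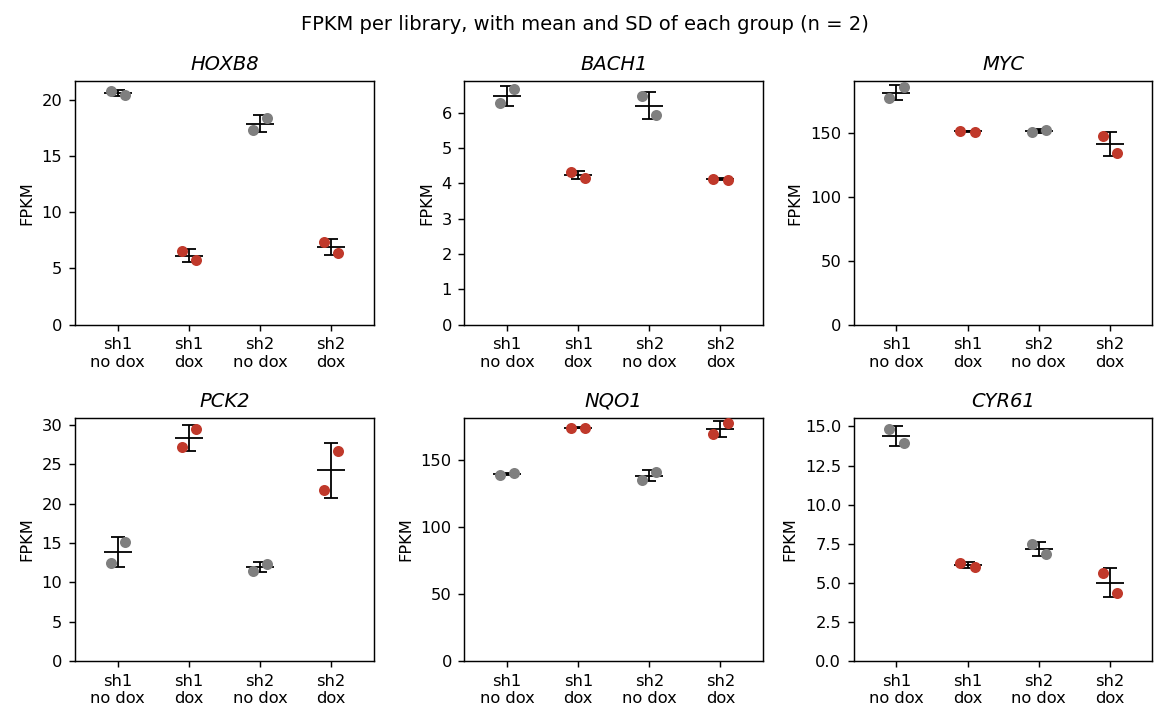
FPKM of HOXB8, BACH1, MYC, PCK2, NQO1 and CYR61 in each of the 8 libraries, by hairpin and doxycycline state; points are libraries (red with doxycycline), the bar is the group mean and the whisker its SD (n = 2). The dox libraries read 5.74 to 7.39 FPKM for HOXB8 against 17.3 to 20.8 without, and 4.09 to 4.32 FPKM for BACH1 against 5.93 to 6.68.

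Averaged over both hairpins, 1906 of 11712 genes changed, 1180 higher and 726 lower. Their median absolute log2 change was 0.19, and 1905 of them had the same sign in both lines. Apart from HOXB8, the largest fall was that of KRTAP2-3, a keratin-associated protein gene, from 30.3 ± 10.8 to 13.6 ± 2.05 FPKM (SD, n = 4 per state; log2 change -1.05, SE 0.05, adjusted p = 2.68e-06). CYR61, a secreted matrix protein gene and a target of the YAP pathway, fell from 10.8 ± 4.18 to 5.58 ± 0.836 FPKM (log2 change -0.78, SE 0.07, adjusted p = 1.30e-04). The immediate early transcription factor gene EGR1 fell from 24.5 ± 0.382 to 14.3 ± 2.69 FPKM (log2 change -0.75, SE 0.06, adjusted p = 1.10e-04). TMEM64 fell from 15.2 ± 0.58 to 9.09 ± 0.89 FPKM (log2 change -0.69, SE 0.06, adjusted p = 1.52e-04). CPA4, a carboxypeptidase gene, fell from 38 ± 11.3 to 23.3 ± 5.49 FPKM (log2 change -0.66, SE 0.04, adjusted p = 8.74e-06). The matrix protein genes CTGF (-0.62, adjusted p = 0.00134) and THBS1 (-0.60, adjusted p = 0.00183) fell as well. So did the small GTPase gene RHOB (-0.58, adjusted p = 2.51e-04), TNS4 of focal adhesions (-0.57, adjusted p = 3.55e-04) and TMED2 of secretory transport (-0.56, adjusted p = 3.30e-05). LOC102723360, a gene model of uncertain mapping, also fell (-0.61, adjusted p = 0.0475). The call of LOC102723360 was lost without sh1-dox-r2 (0.072), sh1-no-dox-r1 (0.133), sh1-no-dox-r2 (0.0714), sh2-dox-r2 (0.136), sh2-no-dox-r1 (0.135) or sh2-no-dox-r2 (0.104). CPA4 (adjusted p = 0.0544), CTGF (adjusted p = 0.0651), THBS1 (adjusted p = 0.144) and LOC102723360 (adjusted p = 0.0656) lost the call with no term for the line. With no filter on low values LOC102723360 (adjusted p = 0.163) no longer passed. LOC102723360 (adjusted p = 0.0606) did not pass with a pseudocount of 0.1. With no trend in the moderation the call ended for LOC102723360 (adjusted p = 0.084). LOC102723360 (adjusted p = 0.111) lost the call with robust moderation.

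The largest rise was that of PCK2, the gene of mitochondrial phosphoenolpyruvate carboxykinase, from 12.9 ± 1.59 to 26.3 ± 3.24 FPKM (SD, n = 4 per state; log2 change 0.97, SE 0.07, adjusted p = 5.41e-05). ASNS, asparagine synthetase, rose from 75.8 ± 11.5 to 136 ± 23.4 FPKM (log2 change 0.83, SE 0.10, adjusted p = 7.04e-04). DDIT4, whose product inhibits mTORC1 under stress, rose from 53 ± 7.67 to 94.1 ± 14.9 FPKM (log2 change 0.81, SE 0.10, adjusted p = 7.61e-04). CHAC1, a glutathione-degrading enzyme gene, rose from 4.39 ± 0.90 to 8.5 ± 2.36 FPKM (log2 change 0.80, SE 0.07, adjusted p = 1.52e-04). DBP, a circadian transcription factor gene, rose from 9.18 ± 3.29 to 16 ± 4.53 FPKM (log2 change 0.76, SE 0.07, adjusted p = 2.18e-04). Rises were also seen in PHGDH of serine synthesis (0.67, adjusted p = 8.74e-04) and the stress cytokine gene GDF15 (0.63, adjusted p = 7.58e-04). The growth factor gene FGF19 (0.61, adjusted p = 2.94e-05), the pseudokinase gene TRIB3 (0.60, adjusted p = 0.00159) and the interferon-stimulated gene OASL (0.59, adjusted p = 0.0132) rose too. So did the read-through gene ABHD14A-ACY1 (0.80, adjusted p = 0.0268) and the near copy U2AF1L5 of U2AF1 (0.71, adjusted p = 0.020), whose reads are hard to assign. The call of ABHD14A-ACY1 was lost without sh1-dox-r2 (0.0962), sh1-no-dox-r1 (0.0582), sh1-no-dox-r2 (0.0716) or sh2-dox-r2 (0.0594). The call of U2AF1L5 was lost without sh1-dox-r1 (0.0588), sh1-no-dox-r1 (0.0658) or sh2-no-dox-r2 (0.0667). With no term for the line DBP (adjusted p = 0.0578), ABHD14A-ACY1 (adjusted p = 0.0533) and U2AF1L5 (adjusted p = 0.0638) no longer passed. ABHD14A-ACY1 (adjusted p = 0.117), U2AF1L5 (adjusted p = 0.104) and OASL (adjusted p = 0.0732) did not pass with no filter on low values. With a pseudocount of 0.1 the call ended for ABHD14A-ACY1 (adjusted p = 0.077). ABHD14A-ACY1 (adjusted p = 0.0553) lost the call with no trend in the moderation. With robust moderation ABHD14A-ACY1 (adjusted p = 0.0748) and U2AF1L5 (adjusted p = 0.115) no longer passed.

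Of all tested genes, 3767 had an unadjusted p under 0.05. On log2(FPKM + 1), which shrinks changes of low values, HOXB8 and KRTAP2-3 were the 2 genes called lower past a 2-fold change, and 0 genes were called higher past it by limma. The higher share of the calls was 61.9% as deposited, 50.3% with quantile normalization (923 higher, 912 lower) and 46.3% with TMM factors (875 higher, 1016 lower). In 5 cases leaving out 1 library moved the count of 1906 by over 1.5 times, to 975 without sh1-dox-r2, 851 without sh1-no-dox-r1, 1167 without sh1-no-dox-r2, 900 without sh2-no-dox-r1 and 1194 without sh2-no-dox-r2.

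The ATF4 and integrated stress response list holds genes of amino acid synthesis, amino acid transport and tRNA charging. Of its 44 tested genes 36 rose, 0 fell by limma and 8 did not pass. In the ATF4 list 38 were higher and 0 lower adjusted over the list alone. The ATF4 list had a median of 0.24, adjusted p = 8.24e-21 by camera and adjusted p = 0.145 with an estimated correlation. Beside PCK2, CHAC1, ASNS and DDIT4, the hormone gene STC2 (0.42, adjusted p = 1.10e-04) and PSAT1 of serine synthesis (0.53, adjusted p = 2.09e-04) rose. The message of ATF4 itself rose from 267 ± 16.3 to 316 ± 30.7 FPKM (SD, n = 4 per state; log2 change 0.24, SE 0.04, adjusted p = 0.00365).

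Of 40 tested interferon-stimulated genes 22 rose and 1 fell. The interferon counts adjusted over the list alone were 25 higher and 1 lower. The interferon list had a median of 0.16, adjusted p = 7.70e-07 by camera and adjusted p = 0.145 with an estimated correlation. The ubiquitin-like modifier gene ISG15 (0.32, adjusted p = 0.00103) and its conjugating enzyme gene UBE2L6 (0.32, adjusted p = 4.78e-04) rose. IFI27 was the member that fell (-0.47, adjusted p = 0.00283).

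Of 26 tested antioxidant and heme genes regulated by BACH1 and NRF2, 14 rose and 1 fell. With members adjusted over the list alone, the BACH1 and NRF2 list had 14 higher and 1 lower. The BACH1 and NRF2 list had a median of 0.12, adjusted p = 6.13e-05 by camera and adjusted p = 0.107 with an estimated correlation. NQO1, a quinone reductase gene, rose from 139 ± 2.62 to 174 ± 3.47 FPKM (SD, n = 4 per state; log2 change 0.32, SE 0.03, adjusted p = 1.63e-04). The transporter genes ABCC2 (0.40, adjusted p = 2.44e-04) and SLC7A11 (0.48, adjusted p = 3.79e-04) rose, as did OSGIN1 (0.42, adjusted p = 6.64e-04). HMOX1, heme oxygenase, rose from 10.6 ± 0.401 to 13.5 ± 0.579 FPKM (log2 change 0.33, SE 0.04, adjusted p = 0.00138). The ferritin genes FTH1 (0.46) and FTL (0.24) rose too, though both have many processed pseudogenes. TXNRD1 was the member that fell (-0.16, adjusted p = 0.00677).

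Of 76 cytosolic ribosomal protein genes 14 rose and 0 fell by limma. For ribosomal protein genes the numbers adjusted over the list alone were 24 higher and 0 lower. The ribosomal protein list had a median of 0.06, adjusted p = 5.12e-06 by camera and adjusted p = 0.461 with an estimated correlation. RPS19 (0.15, adjusted p = 0.00854), RPS2 (0.16, adjusted p = 0.00889), RPL35 (0.13, adjusted p = 0.00947) and RPL13A (0.13, adjusted p = 0.0143) rose. With quantile normalization RPS2 had a change of 0 to within rounding. That method gives equal ranks the same value in every library, so its lost call there can come from the method. RPL13A (adjusted p = 0.075) did not pass with no term for the line. With no filter on low values the call ended for RPS19 (adjusted p = 0.061), RPS2 (adjusted p = 0.105), RPL35 (adjusted p = 0.0539) and RPL13A (adjusted p = 0.089). RPS2 and RPL35 (adjusted p = 0.268) lost the call with quantile normalization. With no trend in the moderation RPL13A (adjusted p = 0.0517) no longer passed. The call of RPS2 was lost without sh1-no-dox-r1 (0.0551). The call of RPL35 was lost without sh1-no-dox-r1 (0.0521). The call of RPL13A was lost without sh1-dox-r2 (0.0703), sh1-no-dox-r1 (0.0794) or sh2-no-dox-r1 (0.0509).

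Of 24 HOX cluster genes other than HOXB8, 8 rose and 0 fell by limma, while the list did not pass. In the HOX list 9 were higher and 0 lower adjusted over the list alone. The HOX list had a median of 0.07, adjusted p = 0.0876 by camera and adjusted p = 0.499 with an estimated correlation. HOXA9 rose from 38 ± 0.918 to 46.3 ± 2.57 FPKM (SD, n = 4 per state; log2 change 0.28, SE 0.03, adjusted p = 4.74e-04). HOXA10 (0.21, adjusted p = 0.00886), HOXA3 (0.29, adjusted p = 0.0181) and HOXD8 (0.31, adjusted p = 0.0235) rose too. The call of HOXA3 was lost without sh1-dox-r2 (0.053), sh1-no-dox-r1 (0.052) or sh1-no-dox-r2 (0.0529). The call of HOXD8 was lost without sh1-dox-r1 (0.0699), sh1-no-dox-r1 (0.055), sh1-no-dox-r2 (0.0734), sh2-dox-r1 (0.0514) or sh2-no-dox-r2 (0.0816). HOXA3 (adjusted p = 0.0765) and HOXD8 (adjusted p = 0.0837) did not pass with no filter on low values. The list passed without sh2-dox-r2 (0.0162) and without sh2-no-dox-r1 (0.0287).

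Genes of cholesterol synthesis and uptake mostly fell, 14 of 26 tested, and 3 rose. The cholesterol counts adjusted over the list alone were 3 higher and 16 lower. The cholesterol list had a median of -0.12, adjusted p = 1.13e-07 by camera and adjusted p = 0.107 with an estimated correlation. INSIG1 (-0.39, adjusted p = 4.18e-04), HMGCS1 (-0.31, adjusted p = 0.00106) and IDI1 (-0.32, adjusted p = 0.00125) fell. The members that rose were TM7SF2 (0.37), SREBF1 (0.18) and PMVK (0.18).

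Of 47 MYC targets 19 fell and 0 rose by limma. With members adjusted over the list alone, the MYC target list had 1 higher and 30 lower. The MYC target list had a median of -0.11, adjusted p = 3.08e-12 by camera and adjusted p = 0.264 with an estimated correlation. LDHA of lactate production (-0.23, adjusted p = 0.00124) and the ribosome biogenesis genes UTP20 (-0.37, adjusted p = 0.00208) and DDX21 (-0.18, adjusted p = 0.00575) fell, beside MYC itself. With no term for the line the call ended for DDX21 (adjusted p = 0.0752). Of 49 G2/M and mitosis genes 20 fell and 0 rose by limma. For G2/M genes the numbers adjusted over the list alone were 1 higher and 27 lower. The G2/M list had a median of -0.10, adjusted p = 5.24e-13 by camera and adjusted p = 0.145 with an estimated correlation. The cytokinesis gene ANLN (-0.31, adjusted p = 0.00262) and the ubiquitin-conjugating enzyme gene UBE2C (-0.21, adjusted p = 0.00327) fell, as did the spindle genes TPX2 (-0.16) and KIF23 (-0.18).

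Of 56 G1/S and DNA replication genes 6 fell and 1, LIG1 (0.10), rose. In the G1/S list 0 were higher and 2 lower adjusted over the list alone. The G1/S list had a median of -0.07, adjusted p = 1.68e-05 by camera and adjusted p = 0.495 with an estimated correlation. RFC1 (-0.16, adjusted p = 0.0172) and RFC5 (-0.20, adjusted p = 0.0182) of the clamp loader fell. MCM10 (-0.20, adjusted p = 0.0289) and GINS2 (-0.13, adjusted p = 0.0337) of the replication fork fell too. The call of RFC1 was lost without sh1-dox-r2 (0.0654), sh1-no-dox-r1 (0.0631), sh1-no-dox-r2 (0.050) or sh2-no-dox-r1 (0.0739). The call of RFC5 was lost without sh1-dox-r2 (0.0691), sh1-no-dox-r2 (0.0646) or sh2-no-dox-r1 (0.0715). The call of MCM10 was lost without sh1-dox-r2 (0.10), sh1-no-dox-r1 (0.0959), sh1-no-dox-r2 (0.057), sh2-dox-r2 (0.0596), sh2-no-dox-r1 (0.0973) or sh2-no-dox-r2 (0.0705). The call of GINS2 was lost without sh1-dox-r2 (0.117), sh1-no-dox-r1 (0.123), sh1-no-dox-r2 (0.0653), sh2-dox-r2 (0.082), sh2-no-dox-r1 (0.116) or sh2-no-dox-r2 (0.0655). MCM10 (adjusted p = 0.0625) lost the call with no term for the line. With no filter on low values RFC5 (adjusted p = 0.0725), MCM10 (adjusted p = 0.0944) and GINS2 (adjusted p = 0.0767) no longer passed. MCM10 (adjusted p = 0.0553) and GINS2 (adjusted p = 0.0741) did not pass with no trend in the moderation.

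Of 35 ERK, AP-1 and immediate early genes 12 fell and 1, ETV5 (0.14), rose. The ERK and AP-1 counts adjusted over the list alone were 2 higher and 12 lower. The ERK and AP-1 list had a median of -0.07, adjusted p = 8.58e-06 by camera and adjusted p = 0.145 with an estimated correlation. Beside EGR1, the transcription factor gene KLF6 (-0.34, adjusted p = 0.00127), the growth factor gene EREG (-0.30, adjusted p = 0.00136) and the phosphatase gene DUSP5 (-0.35, adjusted p = 0.00153) fell. Of 38 glycolysis and hypoxia genes 13 fell and 2 rose. With members adjusted over the list alone, the glycolysis and hypoxia list had 2 higher and 17 lower. The glycolysis and hypoxia list had a median of -0.08, adjusted p = 1.43e-05 by camera and adjusted p = 0.145 with an estimated correlation. The glucose transporter gene SLC2A1 (-0.26, adjusted p = 0.00166) and PFKP (-0.19, adjusted p = 0.00254) fell beside LDHA. The hypoxia-induced genes ADM (0.23) and VEGFA (0.19) rose.

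Of 18 mesenchymal and EMT (epithelial to mesenchymal transition) genes 5 fell and 0 rose by limma. For EMT genes the numbers adjusted over the list alone were 2 higher and 5 lower. The EMT list had a median of -0.05, adjusted p = 0.0186 by camera and adjusted p = 0.145 with an estimated correlation. The 5 were CYR61, CTGF, THBS1, the receptor kinase gene AXL (-0.24, adjusted p = 0.00856) and the repressor gene SNAI1 (-0.25, adjusted p = 0.013). Of these CYR61, CTGF and THBS1 are YAP or TGF-beta targets rather than markers of a mesenchymal state. The list no longer passed with a minimum of 5 FPKM (adjusted p = 0.0591), with no term for the line (adjusted p = 0.0649) or without members of other lists (adjusted p = 0.115). With no term for the line the call ended for AXL (adjusted p = 0.161), CTGF (adjusted p = 0.0651) and THBS1 (adjusted p = 0.144).

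Of 39 epithelial adhesion and junction genes 10 rose and 4 fell, while the list did not pass. In the epithelial list 18 were higher and 8 lower adjusted over the list alone. The epithelial list had a median of 0.10, adjusted p = 0.0876 by camera and adjusted p = 0.461 with an estimated correlation. CDH1, the E-cadherin gene, rose from 21 ± 0.549 to 25.1 ± 0.867 FPKM (SD, n = 4 per state; log2 change 0.24, SE 0.04, adjusted p = 0.0029), and the tight junction gene TJP3 also rose (0.43, adjusted p = 5.86e-04). The keratin genes KRT8 (-0.24) and KRT18 (-0.29), the integrin gene ITGA6 (-0.24) and the splicing regulator gene ESRP2 (-0.16) fell. KRT8 (adjusted p = 0.11) and KRT18 (adjusted p = 0.0586) lost the call with no term for the line. The list passed with quantile normalization (adjusted p = 0.0392) but not with TMM factors. It also passed without sh2-dox-r1 (0.0252) or sh2-no-dox-r2 (0.0449).

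Of 25 proteases and inhibitors of matrix breakdown 6 rose and 1, the sheddase gene ADAM9 (-0.12), fell. The protease counts adjusted over the list alone were 8 higher and 2 lower. The protease list had a median of 0.02, adjusted p = 0.298 by camera and adjusted p = 0.456 with an estimated correlation. The lysosomal protease gene CTSD rose (0.21, adjusted p = 0.00142), and so did the protease inhibitor gene SPINT1 (0.17, adjusted p = 0.0117). MMP11, a matrix metalloprotease gene, rose from 3.29 ± 0.357 to 4.17 ± 0.544 FPKM (SD, n = 4 per state; log2 change 0.26, SE 0.06, adjusted p = 0.0127). The call of SPINT1 was lost without sh1-no-dox-r1 (0.0553). The call of MMP11 was lost without sh2-no-dox-r1 (0.0552). With no term for the line MMP11 (adjusted p = 0.0662) no longer passed. Of 7 invasion genes reported as BACH1 targets, CDK6 (-0.31, adjusted p = 0.00284) and HK2 (-0.24, adjusted p = 0.0153) fell, HMGA2 rose (0.16, adjusted p = 0.00968) and 4 did not pass. FZD1 was among the latter (0.09, adjusted p = 0.179). With members adjusted over the list alone, the invasion list had 1 higher and 2 lower. The invasion list had a median of 0.02, adjusted p = 0.575 by camera and adjusted p = 0.735 with an estimated correlation. The sign of its median was opposite to that of its mean, -0.04, and of the test. That median turned negative with quantile normalization (-0.0222) and with TMM factors (-0.00488). The call of HK2 was lost without sh1-dox-r2 (0.0581), sh1-no-dox-r1 (0.0635) or sh2-no-dox-r1 (0.066). HK2 (adjusted p = 0.0651) did not pass with no filter on low values.

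Of 34 p53 targets 8 rose and 1, PLK2 (-0.49, adjusted p = 5.45e-04), fell. For p53 genes the numbers adjusted over the list alone were 10 higher and 2 lower. The p53 list had a median of 0.03, adjusted p = 0.0775 by camera and adjusted p = 0.206 with an estimated correlation. The pro-apoptotic gene BBC3 rose from 14.9 ± 0.70 to 22.8 ± 0.615 FPKM (SD, n = 4 per state; log2 change 0.59, SE 0.04, adjusted p = 3.80e-05), and TP53INP1 rose too (0.33, adjusted p = 0.00116). The p53 list passed with quantile normalization (adjusted p = 0.0488), though not with TMM factors, and with no term for the line (adjusted p = 0.0483). It also passed without sh2-dox-r2. Of 21 Wnt and beta-catenin targets 5 fell and 1, CEMIP (0.36), rose. In the Wnt list 2 were higher and 6 lower adjusted over the list alone. The Wnt list had a median of -0.02, adjusted p = 0.0892 by camera and adjusted p = 0.456 with an estimated correlation. Those that fell were the Wnt inhibitor gene DKK1 (-0.48), the cyclin gene CCND1 (-0.20), BMP4 (-0.29), AMOTL2 (-0.40) and TCF7 (-0.15). With no term for the line the call ended for CCND1 (adjusted p = 0.16) and AMOTL2 (adjusted p = 0.0788). The Wnt list passed without sh1-dox-r2 (0.0487) and with a minimum of 5 FPKM (adjusted p = 0.037).

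Of 21 TGF-beta response genes 4 rose and 3 fell. The TGF-beta counts adjusted over the list alone were 7 higher and 3 lower. The TGF-beta list had a median of 0.08, adjusted p = 0.378 by camera and adjusted p = 0.461 with an estimated correlation. The inhibitor gene SMAD7 (0.42), ID3 (0.39), ID1 (0.33) and TGIF1 (0.11) rose, while CTGF, THBS1 and BMP4 (-0.29) fell. Without members of other lists the TGF-beta list passed (adjusted p = 0.00713). Of 29 unfolded protein response genes 4 rose and 0 fell by limma. With members adjusted over the list alone, the unfolded protein list had 3 higher and 0 lower. The unfolded protein list had a median of 0.04, adjusted p = 0.232 by camera and adjusted p = 0.411 with an estimated correlation. They were CREB3L2 (0.31), SEC24D (0.26), EDEM1 (0.24) and ERN1 (0.18). The call of ERN1 was lost without sh1-dox-r1 (0.0823), sh1-dox-r2 (0.126), sh1-no-dox-r1 (0.108), sh1-no-dox-r2 (0.129), sh2-dox-r2 (0.136), sh2-no-dox-r1 (0.144) or sh2-no-dox-r2 (0.0755). ERN1 (adjusted p = 0.0706) lost the call with no term for the line. With no filter on low values ERN1 (adjusted p = 0.101) no longer passed. ERN1 (adjusted p = 0.0997) did not pass with quantile normalization. With TMM factors the call ended for ERN1 (adjusted p = 0.0665).

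Of 76 nuclear genes of oxidative phosphorylation (OXPHOS) 8 rose and 2 fell. For OXPHOS genes the numbers adjusted over the list alone were 8 higher and 2 lower. The OXPHOS list had a median of 0.03, adjusted p = 0.0755 by camera and adjusted p = 0.461 with an estimated correlation. UQCRFS1 of complex III fell most (-0.39, adjusted p = 1.30e-04), COX7B fell too (-0.10), and COX8A rose (0.13, adjusted p = 0.00714). The OXPHOS list passed with quantile normalization (adjusted p = 0.00138) but not with TMM factors. It passed as well with no filter (adjusted p = 0.0208), with a minimum of 5 FPKM (adjusted p = 0.0471) and with a term for the replicate number (adjusted p = 0.0478). The same held without sh1-dox-r2 (0.0401), sh2-dox-r2 (0.00998) or sh2-no-dox-r2 (0.0449). Of 20 TNF and NF-kB inflammatory genes, NFKBIA (0.20, adjusted p = 0.0148) and CXCL16 (0.15, adjusted p = 0.0381) rose and RELB fell (-0.18, adjusted p = 0.0493). In the TNF list 1 were higher and 0 lower adjusted over the list alone. The TNF list had a median of 0.03, adjusted p = 0.989 by camera and adjusted p = 0.989 with an estimated correlation. The call of NFKBIA was lost without sh1-dox-r2 (0.0575), sh1-no-dox-r2 (0.0561) or sh2-no-dox-r1 (0.066). The call of CXCL16 was lost without sh1-dox-r1 (0.0832), sh1-dox-r2 (0.0917), sh1-no-dox-r1 (0.11), sh1-no-dox-r2 (0.0858), sh2-dox-r1 (0.0664) or sh2-no-dox-r2 (0.127). The call of RELB was lost without sh1-dox-r1 (0.0956), sh1-dox-r2 (0.114), sh1-no-dox-r1 (0.0765), sh1-no-dox-r2 (0.148), sh2-dox-r2 (0.137), sh2-no-dox-r1 (0.062) or sh2-no-dox-r2 (0.153). CXCL16 (adjusted p = 0.112) and RELB (adjusted p = 0.0986) lost the call with no term for the line. With no filter on low values NFKBIA (adjusted p = 0.0527), CXCL16 (adjusted p = 0.0981) and RELB (adjusted p = 0.124) no longer passed. CXCL16 (adjusted p = 0.0588) did not pass with TMM factors. With no trend in the moderation the call ended for CXCL16 (adjusted p = 0.0781) and RELB (adjusted p = 0.0616).

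Of 7 colonic differentiation genes, KLF5 fell (-0.33, adjusted p = 5.69e-04) and 6 did not pass, among them CA2 (-0.03, adjusted p = 0.64). The colonic counts adjusted over the list alone were 0 higher and 1 lower. The colonic list had a median of 0.02, adjusted p = 0.378 by camera and adjusted p = 0.499 with an estimated correlation. The mean of -0.02 and the test pointed to lower, against the median, which turned negative with quantile normalization (-0.00925) and with TMM factors (-0.00148). The fibroblast and immune markers were listed as genes that epithelial cells do not make. Even so 5 averaged at least 1 FPKM in these HCT116 cells and were tested, and 0 passed by limma. PTPRC (0.19, unadjusted p = 0.0219) and the haemoglobin gene HBA1 (-0.54, unadjusted p = 0.0195) had the 2 unadjusted p values under 0.05. Their adjusted p was 0.0912 and 0.0851. HBA1 passed with a term for the replicate number (adjusted p = 0.0396) and without sh1-dox-r2 (0.0474) or sh2-dox-r2 (0.0242), and PTPRC with no trend in the moderation (adjusted p = 0.0474). With members adjusted over the list alone, the fibroblast and immune list had 0 higher and 0 lower. The fibroblast and immune list had a median of 0.03, adjusted p = 0.989 by camera and adjusted p = 0.989 with an estimated correlation. Here the mean was -0.04, and the median turned negative with quantile normalization (-0.00426).

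By camera with its preset correlation 11 of the 23 lists passed, 4 towards higher and 7 towards lower. With an estimated correlation 0 lists passed by camera, and the lowest adjusted p was 0.107. That form of the test rests on the 4 residual degrees of freedom, which can raise a low p even without a high correlation. The BACH1 and NRF2 list had an estimated correlation of -0.014, below the preset 0.01. Its unadjusted p by camera still went from 2.67e-05 to 0.00933. Some other estimates lay above the preset, as for ATF4 (0.335), MYC target (0.393), ribosomal protein (0.444) and G1/S genes (0.594). For those lists the low p by camera rests on a preset below the estimated correlation. By fry 14 of 23 passed, a test of whether a list moves on balance in 1 direction, which does not compare it with other genes.

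**Figure D2:**
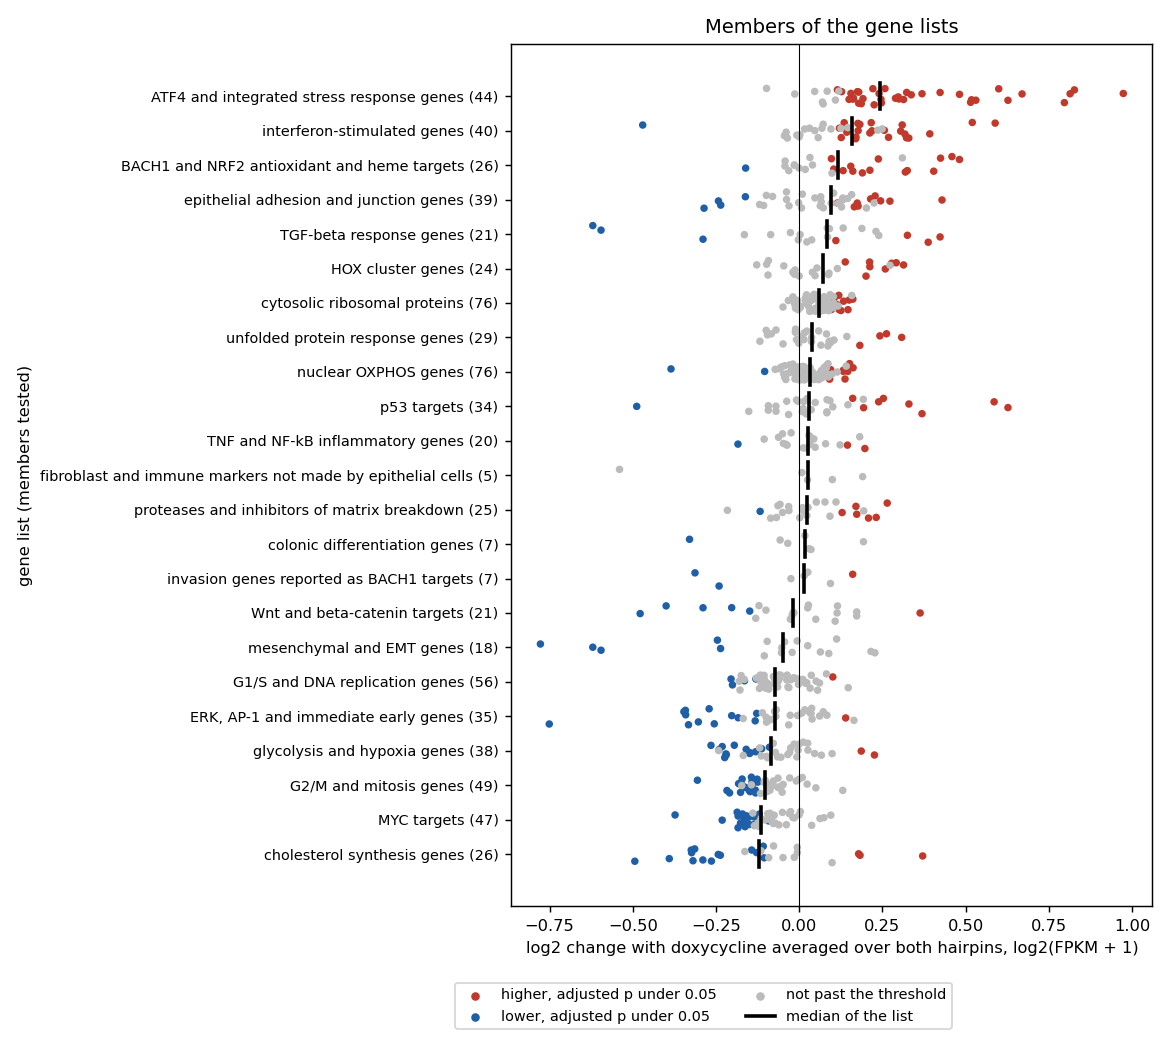
Log2 change with doxycycline, averaged over both hairpins, of each tested member (points) of 23 gene lists, with the number tested in brackets and the list median as a black bar; red and blue points had an adjusted p under 0.05. Medians ran from -0.12 for cholesterol synthesis to 0.24 for the ATF4 list, and those of the invasion, colonic and fibroblast and immune lists (0.02, 0.02 and 0.03) changed sign with quantile normalization.

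Annotation terms carried in the table were tested against 10349 annotated genes by Fisher's exact test, and 3 of 888 terms were enriched among the higher genes and 8 among the lower. That test takes genes as independent, though members of a term can change together, so its p can be too small. It was run only on the calls from the values as deposited, not on those of the alternatives. Higher genes were enriched in endoplasmic reticulum part (22 of 63 genes, 6.42 expected by chance, adjusted p = 1.89e-04), with MAN1B1 (0.34), ERP29 (0.26) and P4HB (0.20) among them. They were enriched in lytic vacuole (25 of 105 genes, 10.7 expected by chance, adjusted p = 0.0155), with the lysosomal genes DNASE2 (0.35), CTSD (0.21) and NAGLU (0.28). Cytokine-mediated signaling pathway was the other (16 of 60 genes, 6.11 expected by chance, adjusted p = 0.0382), with ISG15, HLA-B (0.18) and IFIT2 (0.52). Lower genes were enriched in cholesterol metabolic process (12 of 35 genes, 2.24 expected by chance, adjusted p = 8.04e-04). Steroid biosynthetic process was enriched too (9 of 33 genes, 2.11 expected by chance, adjusted p = 0.0321). In 'de novo' protein folding (10 of 31 genes, 1.98 expected by chance, adjusted p = 0.00822) the lower genes included the chaperonin genes CCT8 (-0.15) and CCT5 (-0.14) and the tubulin gene TUBB2A (-0.31). Response to stress (25 of 173 genes, 11.1 expected by chance, adjusted p = 0.0278) held the chaperone gene HSPA4 (-0.20) and FOSL1 (-0.33). That term held more of the higher genes, though not past the threshold (30 of 173 genes, 17.6 expected by chance, adjusted p = 0.162). Mitotic sister chromatid segregation (8 of 25 genes, 1.6 expected by chance, adjusted p = 0.0278) held the condensin genes SMC4 (-0.21) and NCAPH (-0.19). The spindle term was enriched as well (14 of 73 genes, 4.67 expected by chance, adjusted p = 0.0324). Purine ribonucleoside triphosphate catabolic process (29 of 205 genes, 13.1 expected by chance, adjusted p = 0.0155) held the GTPase gene ARF5 (-0.48). Phosphate-containing compound metabolic process (16 of 89 genes, 5.69 expected by chance, adjusted p = 0.0319) held PFKP. Genes named under these terms were chosen after their values were seen.

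In the sh1 line alone 734 genes changed, 434 higher and 300 lower (n = 2 libraries per group), with 2885 at an unadjusted p under 0.05. The excess of higher genes turned with scaling: 284 were higher and 336 lower with quantile normalization, and 259 were higher and 419 lower with TMM factors. HOXB8 fell most (log2 change -1.60, SE 0.08, adjusted p = 7.49e-06). Next were KRTAP2-3 (-1.31, adjusted p = 9.40e-06), CYR61 (-1.11, adjusted p = 3.70e-04), THBS1 (-0.98, adjusted p = 0.00196) and EGR1 (-0.93, adjusted p = 4.61e-04). DDIT4 (1.06, adjusted p = 0.00255), PCK2 (0.99, adjusted p = 9.61e-04), CHAC1 (0.92, adjusted p = 0.00132) and ASNS (0.84, adjusted p = 0.00887) rose most. The read-through gene NEDD8-MDP1 was also among the 5 largest rises (1.01, adjusted p = 0.0428). The call of NEDD8-MDP1 was lost without sh1-dox-r1 (0.144), sh1-dox-r2 (0.14), sh1-no-dox-r1 (0.239), sh1-no-dox-r2 (0.0649), sh2-no-dox-r1 (0.0697) or sh2-no-dox-r2 (0.0694). The call of ASNS was lost without sh1-dox-r2 (0.083) or sh1-no-dox-r1 (0.0754). DDIT4 (adjusted p = 0.0531), ASNS (adjusted p = 0.074) and NEDD8-MDP1 (adjusted p = 0.161) lost the call with no filter on low values. With quantile normalization NEDD8-MDP1 (adjusted p = 0.0676) no longer passed. NEDD8-MDP1 (adjusted p = 0.051) did not pass with TMM factors. With no trend in the moderation the call ended for NEDD8-MDP1 (adjusted p = 0.0843). NEDD8-MDP1 (adjusted p = 0.111) lost the call with robust moderation. Without single libraries the count was 278 without sh1-dox-r1, 117 without sh1-dox-r2, 99 without sh1-no-dox-r1, 145 without sh1-no-dox-r2, 485 without sh2-no-dox-r1 and 489 without sh2-no-dox-r2.

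Of the 44 ATF4 list genes 24 rose in the sh1 line and 0 fell by limma. For ATF4 genes the numbers adjusted over the list alone were 37 higher and 1 lower. The ATF4 list had a median of 0.23, adjusted p = 2.29e-17 by camera and adjusted p = 0.218 with an estimated correlation. Of 40 interferon-stimulated genes 11 rose and 0 fell by limma. The interferon list had a median of 0.17, adjusted p = 5.25e-06 by camera and adjusted p = 0.218 with an estimated correlation. Of 26 BACH1 and NRF2 genes 7 rose and 1 fell, with NQO1 (0.31) and HMOX1 (0.34) among those that rose. The BACH1 and NRF2 list had a median of 0.12, adjusted p = 8.93e-04 by camera and adjusted p = 0.124 with an estimated correlation. Of 35 ERK, AP-1 and immediate early genes 10 fell and 0 rose by limma. The ERK and AP-1 list had a median of -0.09, adjusted p = 9.63e-08 by camera and adjusted p = 0.124 with an estimated correlation. Of 47 MYC targets 11 fell and 0 rose by limma, with 25 lower and 0 higher adjusted over the list alone. The MYC target list had a median of -0.13, adjusted p = 2.12e-13 by camera and adjusted p = 0.256 with an estimated correlation. Of 26 cholesterol genes 9 fell and 0 rose by limma. The cholesterol list had a median of -0.13, adjusted p = 1.29e-06 by camera and adjusted p = 0.124 with an estimated correlation. Of 18 EMT genes 5 fell, CTGF (-0.85) and AXL (-0.37) among them, and 1 rose. The EMT list had a median of -0.08, adjusted p = 0.00232 by camera and adjusted p = 0.136 with an estimated correlation. In all, 12 of 23 lists passed by camera in the sh1 line, and 0 with an estimated correlation. The Wnt list was among the 12 (median -0.03, adjusted p = 0.0286 by camera). Its call was lost with no filter (adjusted p = 0.105), without members of other lists (adjusted p = 0.185) and without sh1-dox-r1.

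In the value table the sh2 line is named sh3, and it was matched to the label sh2 by elimination, which is not proven. In it 297 genes changed, 162 higher and 135 lower (n = 2 libraries per group), with 2185 at an unadjusted p under 0.05. Here too the balance turned, as 136 were higher and 155 lower with quantile normalization and 101 were higher and 152 lower with TMM factors. HOXB8 fell most (log2 change -1.26, SE 0.08, adjusted p = 8.63e-05). Others among the 5 largest falls were KRTAP2-3 (-0.78, adjusted p = 7.72e-04), IFI27 (-0.79, adjusted p = 0.00467) and TMEM64 (-0.62, adjusted p = 0.00569). MAGEA2, 1 of a pair of near-identical copies, also fell (-0.80, adjusted p = 0.0355). PCK2 (0.96, adjusted p = 0.00196), ASNS (0.82, adjusted p = 0.0175), DBP (0.68, adjusted p = 0.00881) and CHAC1 (0.68, adjusted p = 0.00854) rose most. HIST1H2AG, a histone gene whose transcripts mostly lack the selected tail, rose too (0.67, adjusted p = 0.0124). The call of ASNS was lost without sh2-dox-r2 (0.0747) or sh2-no-dox-r1 (0.172). The call of DBP was lost without sh2-no-dox-r1 (0.124). The call of CHAC1 was lost without sh2-dox-r2 (0.0572), sh2-no-dox-r1 (0.103) or sh2-no-dox-r2 (0.0642). The call of HIST1H2AG was lost without sh2-dox-r2 (0.0628), sh2-no-dox-r1 (0.112) or sh2-no-dox-r2 (0.073). The call of MAGEA2 was lost without sh1-dox-r1 (0.0515), sh1-dox-r2 (0.0516), sh2-dox-r1 (0.0656), sh2-dox-r2 (0.127), sh2-no-dox-r1 (0.224) or sh2-no-dox-r2 (0.141). The call of IFI27 was lost without sh2-no-dox-r1 (0.0669). The call of TMEM64 was lost without sh2-no-dox-r1 (0.0981). With no filter on low values PCK2 (adjusted p = 0.050), ASNS (adjusted p = 0.121), DBP (adjusted p = 0.0867), CHAC1 (adjusted p = 0.0843), HIST1H2AG (adjusted p = 0.0659), MAGEA2 (adjusted p = 0.161) and TMEM64 (adjusted p = 0.0765) no longer passed. ASNS (adjusted p = 0.0729) and MAGEA2 (adjusted p = 0.0932) did not pass with no trend in the moderation. With robust moderation the call ended for ASNS (adjusted p = 0.0763) and MAGEA2 (adjusted p = 0.076). Single libraries left out changed the count to 172 without sh1-no-dox-r1, 172 without sh1-no-dox-r2, 98 without sh2-dox-r2, 17 without sh2-no-dox-r1 and 59 without sh2-no-dox-r2.

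Of the 44 ATF4 list genes 23 rose in the sh2 line and 0 fell by limma. In the ATF4 list 33 were higher and 0 lower adjusted over the list alone. The ATF4 list had a median of 0.25, adjusted p = 1.28e-24 by camera and adjusted p = 0.185 with an estimated correlation. Of 26 BACH1 and NRF2 genes 7 rose and 0 fell by limma, NQO1 (0.32, adjusted p = 0.00466) among them. The BACH1 and NRF2 list had a median of 0.13, adjusted p = 4.15e-06 by camera and adjusted p = 0.0735 with an estimated correlation. Of 26 cholesterol genes 7 fell and 0 rose by limma. The cholesterol list had a median of -0.13, adjusted p = 8.58e-08 by camera and adjusted p = 0.0735 with an estimated correlation. Of 38 glycolysis and hypoxia genes 5 fell and 1 rose. The glycolysis and hypoxia list had a median of -0.11, adjusted p = 8.58e-08 by camera and adjusted p = 0.105 with an estimated correlation. Of 49 G2/M genes 2 fell and 0 rose by limma, with 21 lower and 0 higher adjusted over the list alone. The G2/M list had a median of -0.13, adjusted p = 7.71e-14 by camera and adjusted p = 0.191 with an estimated correlation. Of 18 EMT genes 1 fell, and the list did not pass. The EMT list had a median of 0.01, adjusted p = 0.155 by camera and adjusted p = 0.325 with an estimated correlation. The test and the mean of -0.05 pointed to lower, and the median turned to -0.00166 with TMM factors. In all, 11 of 23 lists passed by camera in this line, and 0 with an estimated correlation. The epithelial list was among the 11 (median 0.09, adjusted p = 0.0348 by camera). Its call was lost with a minimum of 5 FPKM (adjusted p = 0.0651) and without sh2-dox-r2 or sh2-no-dox-r1.

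With doxycycline many of the same genes changed in the same direction in both lines. In each line 100 genes were higher, against 6.0 expected if the calls were independent, and 101 were lower, against 3.46. No library had the drug without a hairpin, so the drug alone could also give such agreement. By limma 0 genes were called in opposite directions, against 9.15. PCK2, ASNS and CHAC1 were higher with each, and HOXB8, BACH1, KRTAP2-3, CYR61 (-1.11 and -0.45) and EGR1 (-0.93 and -0.57) lower. Of the genes called in the sh1 line 96.9% had the same sign in the sh2 line, and of those called in the sh2 line 99.3% had the same sign in the sh1 line. Across all tested genes, which are not independent replicates, the log2 changes correlated with Pearson r = 0.617 and Spearman rho = 0.603. Across genes called in the sh1 line the slope of the sh2 change on the sh1 change was 0.608. Genes chosen by their sh1 call tend to have overestimated sh1 changes, which lowers this slope even where the effects are equal.

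**Figure D3:**
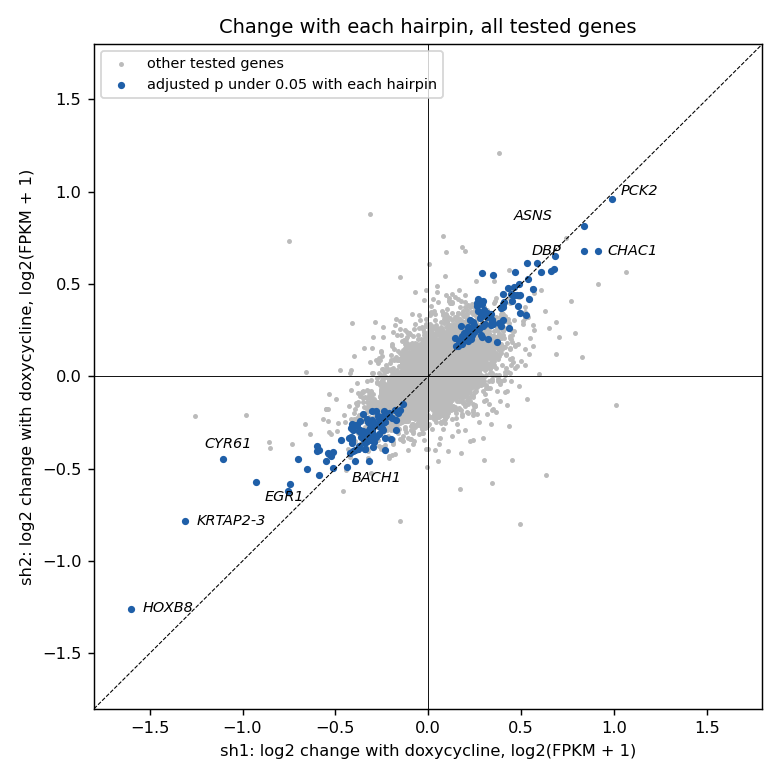
Log2 change with doxycycline of each tested gene in the sh1 line (x axis) and in the sh2 line (y axis), on log2(FPKM + 1); blue points had an adjusted p under 0.05 with each hairpin and the dashed line marks equal changes. HOXB8 lies at -1.60 and -1.26, PCK2 at 0.99 and 0.96.

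Tested directly, 0 genes had a dox effect that differed between the hairpins by limma, with 566 at an unadjusted p under 0.05. HOXB8 fell less in the sh2 line by 0.34 on the log2 scale, a difference not past the threshold (unadjusted p = 0.00871, adjusted p = 0.992). On simulated data this test found 70.3% of genes whose effects differed by 0.5 on the log2 scale. There 200 genes differed and the noise was independent between genes, which eases the adjustment. In the real data MAGEA2, with an unadjusted p of 2.01e-04 by limma, had an adjusted p of 0.686. The 0 calls thus do not show that the hairpins act alike. Without sh1-no-dox-r1 it called 2 genes, MAGEA2 (-1.64, adjusted p = 9.13e-05) and FAM72D (-1.33, adjusted p = 0.0186). Without sh1-no-dox-r2 it called 2, MAGEA2 (-0.94, adjusted p = 0.0166) and PLA2G4B (-1.33, adjusted p = 0.0378); these names were taken after their values were seen. For lists 5 of 23 passed by camera here, those of EMT, MYC target, ribosomal protein, glycolysis and hypoxia, and ERK and AP-1 genes. With an estimated correlation 0 passed by camera, and the lowest adjusted p was 0.35.

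Without doxycycline 170 genes differed between the lines, 97 higher and 73 lower in sh2 than in sh1 (n = 2 libraries per group), with 2116 at an unadjusted p under 0.05. With quantile normalization 63 were higher and 71 lower, and with TMM factors 77 were higher and 117 lower, so this balance turned with scaling as well. HOXB8 read -0.20 on the log2 scale in sh2 relative to sh1, not past the threshold (adjusted p = 0.203), and MYC was lower (-0.26, adjusted p = 0.0315). Among the 5 genes furthest below sh1 were THBS1 (-1.08, adjusted p = 0.00312), CYR61 (-0.91, adjusted p = 0.00207), KRTAP2-3 (-0.87, adjusted p = 5.44e-04) and KRT80 (-0.82, adjusted p = 0.0188). TMEM183B, which has a near copy, was the lowest of them (-1.14, adjusted p = 0.0361). Furthest above were DBP (0.82, adjusted p = 0.00516), ALDOC (0.69, adjusted p = 0.00182) and PNRC1 (0.66, adjusted p = 0.00312). PTP4A3 (0.61, adjusted p = 0.0137) and SAT1 (0.61, adjusted p = 0.00369) followed. The call of DBP was lost without sh1-no-dox-r2 (0.0543) or sh2-no-dox-r2 (0.0775). The call of PTP4A3 was lost without sh1-no-dox-r2 (0.0982), sh2-no-dox-r1 (0.0924) or sh2-no-dox-r2 (0.13). The call of SAT1 was lost without sh2-no-dox-r1 (0.0594) or sh2-no-dox-r2 (0.0502). The call of THBS1 was lost without sh2-no-dox-r1 (0.0531). The call of KRT80 was lost without sh1-no-dox-r1 (0.0526), sh1-no-dox-r2 (0.148), sh2-no-dox-r1 (0.148) or sh2-no-dox-r2 (0.0864). The call of TMEM183B was lost without sh1-no-dox-r1 (0.0703), sh1-no-dox-r2 (0.224) or sh2-no-dox-r2 (0.16). DBP (adjusted p = 0.0941), PTP4A3 (adjusted p = 0.0998), SAT1 (adjusted p = 0.0713), THBS1 (adjusted p = 0.0667), CYR61 (adjusted p = 0.0513), KRT80 (adjusted p = 0.124) and TMEM183B (adjusted p = 0.163) lost the call with no filter on low values. With a pseudocount of 0.1 TMEM183B (adjusted p = 0.0533) no longer passed. TMEM183B (adjusted p = 0.0846) did not pass with no trend in the moderation. With robust moderation the call ended for TMEM183B (adjusted p = 0.0592). The count with 1 library left out was 29 without sh1-no-dox-r1, 17 without sh1-no-dox-r2, 361 without sh2-dox-r1, 361 without sh2-dox-r2, 16 without sh2-no-dox-r1 and 18 without sh2-no-dox-r2.

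Of 38 glycolysis and hypoxia genes 9 were higher in untreated sh2 than in sh1 and 0 lower by limma, with 13 higher and 1 lower adjusted over the list alone. The glycolysis and hypoxia list had a median of 0.09, adjusted p = 1.74e-05 by camera and adjusted p = 0.19 with an estimated correlation. Of 26 cholesterol genes 3 were higher and 0 lower by limma. The cholesterol list had a median of 0.09, adjusted p = 3.55e-04 by camera and adjusted p = 0.19 with an estimated correlation. Of 44 ATF4 list genes 4 were lower and 0 higher by limma, with 20 lower adjusted over the list alone. The ATF4 list had a median of -0.15, adjusted p = 2.00e-15 by camera and adjusted p = 0.365 with an estimated correlation. Of 47 MYC targets 4 were lower and 0 higher by limma, with 22 lower and 1 higher adjusted over the list alone. The MYC target list had a median of -0.13, adjusted p = 7.46e-16 by camera and adjusted p = 0.365 with an estimated correlation. In all, 8 lists passed by camera here, the others being the BACH1 and NRF2, G1/S, interferon and ribosomal protein lists, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.19. The call was lost without sh2-no-dox-r2 for the G1/S list (0.0764) and the ribosomal protein list (0.56).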

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

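The list tests and the splits of the samples in this part were chosen before their results were seen, apart from the list tests without members shared with other lists and the splits with no term for the line or within the lines. The dox effect differed between the hairpins for 5 lists by a test of the difference itself, each at the preset correlation and none with an estimated one. The no-dox libraries enter it with the opposite sign to the untreated-line comparison, so noise in them can give such a call. By camera glycolysis and ribosomal protein genes were higher in untreated sh2 than in sh1, and MYC targets lower. Each of these ran opposite to its difference of effects. The EMT list and the ERK and AP-1 list did not pass between the untreated lines. ERK, AP-1 and immediate early genes fell further in the sh1 line (median log2 change -0.09 in sh1 and -0.05 in sh2; adjusted p = 2.13e-04 by camera, and adjusted p = 0.35 with an estimated correlation), and the call was lost without sh2-dox-r2 (adjusted p = 0.0581). MYC targets did so too (median log2 change -0.13 in sh1 and -0.08 in sh2; adjusted p = 0.00293 by camera, and adjusted p = 0.791 with an estimated correlation), and the call was lost without sh2-dox-r1 (adjusted p = 0.854). Mesenchymal and EMT genes were lower in sh1 and near 0 in sh2, where the median turned negative with TMM factors (median log2 change -0.08 in sh1 and 0.01 in sh2; adjusted p = 0.00461 by camera, and adjusted p = 0.35 with an estimated correlation), and the call was lost with no filter on low values (adjusted p = 0.262) and without the members of other lists (adjusted p = 0.079). Glycolysis and hypoxia genes fell further in the sh2 line (median log2 change -0.06 in sh1 and -0.11 in sh2; adjusted p = 0.012 by camera, and adjusted p = 0.487 with an estimated correlation), and the call was lost with no filter (adjusted p = 0.0884) and without sh1-dox-r1 (adjusted p = 0.0841), sh2-dox-r2 (adjusted p = 0.0612) or sh2-no-dox-r1 (adjusted p = 0.0787). Cytosolic ribosomal protein genes rose further in sh1 (median log2 change 0.08 in sh1 and 0.04 in sh2; adjusted p = 0.0206 by camera, and adjusted p = 0.837 with an estimated correlation), and the call was lost with TMM factors (adjusted p = 0.121), with no filter (adjusted p = 0.0906), with no trend (adjusted p = 0.175), and without sh1-dox-r2 (adjusted p = 0.538), sh1-no-dox-r1 (adjusted p = 0.341), sh2-dox-r1 (adjusted p = 0.961) or sh2-no-dox-r2 (adjusted p = 0.674). Lists not past the threshold here passed it under other settings: the Wnt list with a minimum of 5 FPKM (adjusted p = 0.0387), quantile normalization (adjusted p = 0.0313) or a term for the replicate number (adjusted p = 0.0311), and the G2/M list with quantile normalization (adjusted p = 0.0241). With 1 library left out the ATF4 list passed without sh1-no-dox-r1 (adjusted p = 0.0124), sh2-dox-r1 (adjusted p = 0.0139) or sh2-no-dox-r2 (adjusted p = 0.00974). The Wnt list did so without sh2-dox-r2 (adjusted p = 0.0123) or sh2-no-dox-r1 (adjusted p = 0.0403), and the G2/M list without sh1-dox-r2 (adjusted p = 0.00692). The protease list did so without sh2-dox-r1 (adjusted p = 0.028) or sh2-no-dox-r2 (adjusted p = 0.0181), and the epithelial list without sh2-dox-r1 (adjusted p = 0.0151). The G1/S list passed with a higher change in sh2 without sh1-dox-r1 (adjusted p = 0.00353) or sh2-dox-r2 (adjusted p = 1.63e-05) and with a lower one without sh2-dox-r1 (adjusted p = 0.0139).

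The count of genes changed by doxycycline averaged over both hairpins, 1906, was set against all ways to split the 8 libraries into 4 and 4. Of 35 splits, 1 gave as many genes, the real one, and the highest of the others gave 1 gene. With a fit of 2 groups and no term for the line for every split, the real one gave 1074 genes and the highest of the others 1. Of the 18 splits that keep 2 libraries of each line on each side, 1, the real one, gave as many (1906, and at most 1 in the others), and 18 are too few for a share under 0.05. The real split is also the only 1 whose spread is free of the dox effect, which can lower the counts of the others.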

How the results depend on the processing

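Values as in the report came from log2(FPKM + 1) with a minimum mean of 1 FPKM and all 8 libraries; the tests without members of other lists were chosen after seeing the data. The fall of HOXB8 stayed past the threshold under every alternative run, between -1.55 and -1.38, and between -1.47 and -1.38 when 1 library was left out. With no filter, where 17166 genes were tested, the calls were 1021 for the averaged effect, 155 in sh1, 35 in sh2 and 23 between the untreated lines, and the correlation of the hairpins was 0.528. With a minimum of 5 FPKM that correlation was 0.704, and with a pseudocount of 0.1 it was 0.556; both act through genes of low level, by construction. With no term for the line the averaged effect had 1074 calls; there the line difference counts as spread. Moderation without a trend gave 379 calls in sh1, 90 in sh2 and 67 between the untreated lines; the cause was not tested. From its own 4 libraries alone, the sh2 line had 107 calls and the sh1 line 886, with fewer samples for the spread. The difference of effects had 0 calls by limma under each of these that applies to it; no term for the line and the 4 libraries of 1 line were not run for it.

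Leaving out 1 library gave 851 to 2356 calls for the averaged effect, 99 to 1089 in sh1, 17 to 370 in sh2, 0 to 2 for the difference of effects, 16 to 361 between the untreated lines, and a correlation of 0.442 to 0.620 between the hairpins. A group left with 1 library was assumed to vary like the others. In 3 cases the direction of a list test by camera turned, and the cause was not tested. For the G1/S list in the sh2 line it did so without sh2-dox-r2, where the median read 0.0190 (range with each library left out -0.134 to 0.0190). For that list in the difference of effects it did so without sh2-dox-r1, with a median of -0.0808 (range -0.0808 to 0.0642). For the ribosomal list in the difference it did so without sh2-no-dox-r2, though the median stayed negative at -0.0178 (range -0.0704 to -0.0125). For the averaged effect, list tests kept direction and side of the threshold in 393 cases, passed newly in 18 and were lost in 3. They were less stable in the sh2 line (345 kept, 14 newly past, 8 lost, 1 turned) and in the difference of effects (337 kept, 15 newly past, 14 lost, 2 turned). In sh1 356 kept both, 9 passed newly and 3 were lost, and between the untreated lines 362, 4 and 2. Over all comparisons, named genes kept both in 2207 cases, passed newly in 7 and lost their call in 211.

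The repeat numbers were not taken to pair the samples, since the differences between repeats correlated at -0.03 to 0.22 between groups, over 0.1 for some pairs of groups but not for all. Even so, the second repeat lay below the first on the first principal component in every group. The median difference of ATF4 list members was 0.0458 to 0.0735, higher in the second repeat of every group. A difference may thus be shared by repeat number, and fits without a replicate term count it as spread. A replicate block, a term for the replicate number, gave 2684 calls for the averaged effect, within 1.5 times of 1906, and 1362 in sh1, 738 in sh2 and 505 between the untreated lines; the cause was not tested.

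Count-based tests were not run because the table holds no counts, and robust moderation was not run for the lists because camera has no such option. The depth is unknown, so no limit from counts is given for genes of low level.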

Other observations

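The tests of scaling, of the repeats, of doxycycline apart from HOXB8, of the members shared with the ATF4 list and of the difference between the lines were chosen only after the result was seen. The rise of the ATF4 and integrated stress response list was weighed first. A difference in scaling between libraries is argued against, since the list's median was 0.244 with quantile normalization and 0.223 with TMM factors. Each repeat number holds 1 library of every group, so a difference shared by a repeat cancels in the dox comparison by design. What the repeats do show is that the rise did not rest on 1 of them. The median was 0.245 within the first repeats and 0.223 within the second. The differences between repeats of the same group were 0.0458 to 0.0735. An effect of doxycycline on this program apart from HOXB8 cannot be told apart from an effect of lower HOXB8: the list's difference between the hairpins had adjusted p = 0.902 with an estimated correlation, the hairpins lowered HOXB8 by similar amounts, and no library had the drug without a hairpin.

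The rise of antioxidant and heme genes while their repressor BACH1 fell was weighed next. Members shared with the ATF4 list are not the whole source, since without them 25 of 26 remained, with a median of 0.10. These 25 had an unadjusted p = 1.12e-04 by camera, or an unadjusted p = 0.0126 by camera with an estimated correlation. With the latter the whole list had adjusted p = 0.107 over the 23 lists. Since nearly all members stayed, this cannot tell whether the ATF4 program moved them as well. Reads shared with pseudogenes are argued against as the whole source too, since the 16 members with no named pseudogene had a median of 0.176. HMOX1, picked as the best known target of BACH1 after the list was seen to rise but before its own value was, changed by 0.325 on the log2 scale, which is consistent with less repression by BACH1. Doxycycline itself may also act on these genes, which no library here can exclude, so the lower BACH1 stays a hypothesis.

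The difference between the untreated lines was compared with the dox effect across genes, to ask whether the sh2 hairpin may be active before induction. The comparisons share libraries, which alone makes them correlate; the first measure was Pearson's r, which read 0.503 with the sh1 effect (0.502 on average in 100 random draws) and -0.0526 with the sh2 effect (-0.501 in the draws), and covariance was then used in its place. The covariance with the sh1 effect was 0.00919 against 0.00260 to 0.00466 in the draws. In the draws the noise was independent between genes, so their ranges may be too narrow. They cannot exclude the shared libraries as the whole source. The covariance with the sh2 effect was -8.43e-04 against -0.00445 to -0.00245, but HOXB8 itself was not called between the untreated lines (adjusted p = 0.203), so a hairpin active before induction and a difference between the lines of another origin cannot be told apart. Of the 8 lists past the threshold by camera between the untreated lines, 4 ran opposite to the averaged dox effect, with medians of -0.15 for ATF4, -0.08 for BACH1 and NRF2, 0.09 for cholesterol and 0.09 for glycolysis genes, and 4 ran the same way, with -0.13 for MYC targets, -0.04 for G1/S, 0.12 for interferon and 0.06 for ribosomal protein genes, none of them past it with an estimated correlation.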
